A study of Homo sapiens with 6 samples.

How the data were processed

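RNA-seq was performed on KYSE450, an established human esophageal squamous cell carcinoma (ESCC) line, in 2 groups of 3 libraries. Mock libraries came from cells given a mock virus infection, and shHMGB2 libraries from cells infected with a virus that carries a short hairpin RNA against HMGB2. Whether the mock virus carried a hairpin is not given in the sources used here. Total RNA was taken up in Trizol and libraries were built with an mRNA preparation kit, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

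Bowtie2 2.2.5, RSEM 1.2.12 and the genome build hg38 are named in the submitters' processing notes, without a role or an order. The authors deposited 1 table with 27887 rows and 3 kinds of value. Expression per library is given as FPKM with 2 decimals, per the file headers. The deposited group values behave as a normalized signal, since the log2 of their ratio equals the deposited log2 fold change in the table. The authors' deposited p-value and adjusted p-value come from a test whose name is not given in the sources used here. The table marks 76 genes as Up or Down, with an absolute log2 fold change of at least 1.00 and an adjusted p of at most 0.0490 among those marked.

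The deposited table holds no read counts per library. Genes seen in a single library showed group values that were whole multiples of 1 step in 100% of cases (tolerance 0.01), and these steps gave relative depths. The size factors were 0.919, 0.874 and 1.21 for mock replicates 1, 2 and 3, and 1.31, 1.14 and 0.699 for shHMGB2 replicates 1, 2 and 3. Depth estimated with these and the authors' group values was, relative to shHMGB2 replicate 3, 1.31, 1.25 and 1.73 for the mock replicates and 1.88 and 1.64 for shHMGB2 replicates 1 and 2. Whole reads per gene could not be recovered, because 17.2% of reconstructed low values lay within 0.1 of a whole number and chance gives 20%. A count test was therefore not run.

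The main test used log2(FPKM + 1) for the 13409 genes with a mean of at least 1 FPKM over the 6 libraries. Values were fitted with limma 3.58.1 in R 4.3.3 with group as the single term, empirical Bayes moderation with a mean-variance trend, and Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p of 0.05, 2-sided. Fold changes are on the log2(FPKM + 1) scale and understate the change of genes with low values. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. A total of 29 lists were fixed before the data were examined, and 25 had at least 5 measured members and were tested as 1 family.

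The genes named were set by a rule written before the data were examined. It takes the HMGB genes and a few cholesterol genes, among them SREBF2 and SQLE. It adds the 10 largest rises and the 10 largest falls among genes past the threshold that have a gene symbol, at least 5 FPKM in the higher group and no overlap between the groups. From each list it takes the 3 members past the threshold with the largest change, or 5 for the lists of cholesterol synthesis and uptake. Where no member passed, it takes the member with the smallest p. Other genes named were chosen after their values were seen. Some genes that the rule takes are not reported here, though lists and counts include them.

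On simulated data for the comparison of shHMGB2 with mock, run on 13180 genes, the fit called 99 of 100 genes changed by 1 log2 unit and 58 of 100 changed by 0.5, with 10 false calls. Changed genes were taken only from those above a minimum level in mock, and noise was independent between genes. The simulation therefore does not cover changes in genes with the lowest values, or deviations that genes share. Alternatives fixed before the data were examined covered the pseudocount, the filter, 3 scalings, the variance model, library weights, the thresholds, a replicate block and each library left out. Alternatives added later summed copies of a gene, left out rows without a symbol, removed a transcript length trend, or left out genes with a 3' UTR heptamer.

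Transcript lengths and untranslated regions came from GENCODE 29 on GRCh38. Of the table's rows, 17759 matched by symbol and 1199 through a newer symbol. Gene positions are from RefSeq on GRCh38. The table has 2138 rows that are numbered copies of another gene row, 43 of which were called, and 740 rows without a gene symbol, 17 of which were called. Members of near-identical gene families, such as the GAGE, SPRR and keratin genes, share reads that the authors' counting could split between them.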

Results

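Gene expression was measured by RNA-seq in 6 libraries of KYSE450 cells, 3 from mock-infected cells and 3 from cells with HMGB2 knocked down by a hairpin virus. Summed FPKM ranged from 740680 in shHMGB2 replicate 2 to 829440 in mock replicate 1. The estimated depth differed by 1.88-fold between the deepest library, shHMGB2 replicate 1, and the shallowest, shHMGB2 replicate 3. Pearson's r between log2(FPKM + 1) profiles was 0.985 to 0.989 within groups and 0.978 to 0.987 between groups. At most 0.813% of tested genes had equal FPKM in any pair of libraries, so no library was a copy of another.

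HMGB2, which encodes a chromatin protein that binds and bends DNA, was the target of the hairpin. Its level was 115.8, 111.4 and 108.6 FPKM in the mock libraries and 22.1, 24.5 and 27.8 FPKM in the shHMGB2 libraries. The means were 112 ± 3.60 FPKM (SD, n = 3) and 24.8 ± 2.84 FPKM (SD, n = 3), a 4.52-fold lower level that left 22.1% of the mock mean. The log2 fold change was -2.14 (SE 0.084, limma adjusted p = 0.000113). HMGB2 lies on chromosome 4 at 173331376 to 173334358 (GRCh38). Its relatives HMGB1 and HMGB3 had log2 fold changes of 0.02 and 0.02, with adjusted p = 0.857 and 0.843 in limma. Of 10 measured high mobility group genes, 1 was lower, HMGB2, and 1 was higher, HMGA2, an architectural chromatin protein, which went from 14.5 ± 0.749 to 29.4 ± 0.464 FPKM (SD, n = 3 each). Again 1 was higher and 1 was lower when adjusted over the list alone. The list's median log2 fold change was 0.007 and its mean -0.13, and its camera test, which pointed down, did not pass (adjusted p = 0.502).

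**Figure D1:**
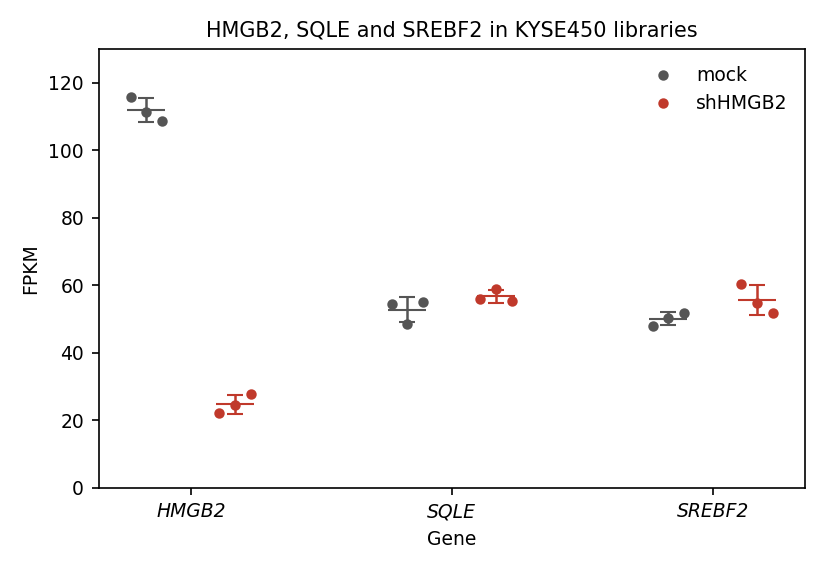
FPKM (vertical axis, linear from 0) of HMGB2, SQLE and SREBF2 in the 6 libraries, with mock in grey and shHMGB2 in red. Points are libraries, horizontal bars are group means and error bars are SD (n = 3). HMGB2 falls from a mean of 112 to 24.8 FPKM, while SQLE and SREBF2 did not pass the limma threshold.

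The series' design text names genes that regulate cholesterol metabolism as its question. Most genes of cholesterol biosynthesis did not pass the threshold after HMGB2 knockdown. Of 21 measured members, 1 was higher, 0 were lower and 20 did not pass. The 1 that rose was LBR, a lamin B receptor with sterol reductase activity, from 32.5 ± 3.01 to 45.5 ± 1.81 FPKM (SD, n = 3 each; log2 fold change 0.48, SE 0.077, limma adjusted p = 0.0147). SQLE, the squalene epoxidase, had 52.8 ± 3.73 FPKM in mock and 56.7 ± 1.94 in shHMGB2 (SD, n = 3 each; limma adjusted p = 0.346). In this list 4 members were higher and 1 was lower when adjusted over the list alone. The list's median log2 fold change was 0.06 (camera adjusted p = 0.374; adjusted p = 0.794 with an estimated correlation). In the authors' deposited table, 2 members of this list were higher and 1 was lower at an adjusted p under 0.05. LBR no longer passed without mock replicate 2 (adjusted p = 0.0604 in limma) or without shHMGB2 replicate 1, 2 or 3 (limma adjusted p = 0.0564, 0.0652 and 0.0549).

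Genes of cholesterol uptake and SREBP regulation moved in both directions. Of 21 measured members, 1 was higher, 2 were lower and 18 did not pass. VLDLR, a lipoprotein receptor, rose from 8.60 ± 1.18 to 13.4 ± 0.955 FPKM (SD, n = 3 each; log2 fold change 0.59, SE 0.10, limma adjusted p = 0.0177). SCARB1, the receptor for high-density lipoprotein, fell from 56.3 ± 3.47 to 39.3 ± 2.22 FPKM (SD, n = 3 each; log2 fold change -0.51, SE 0.069, limma adjusted p = 0.00729). SREBF2, the transcription factor of sterol synthesis, had a log2 fold change of 0.15 (SE 0.071, limma adjusted p = 0.222). Adjusted over the list alone, 1 member was higher and 4 were lower. In the authors' deposited table, 2 members of this list were higher and 7 were lower at an adjusted p under 0.05. The list's median log2 fold change was 0.003 and its mean -0.03, opposite in sign, and its camera test, which pointed down, did not pass (adjusted p = 0.362). VLDLR no longer passed without shHMGB2 replicate 1, 2 or 3 (limma adjusted p = 0.0751, 0.0627 and 0.0569). The count of lower members was 1 without mock replicate 2 or without shHMGB2 replicate 1, 2 or 3.

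Neighbouring lipid lists moved little. Of 10 measured genes of cholesterol efflux and LXR targets, 0 passed in limma. NR1H2, an oxysterol receptor, had the smallest p there, with 18.1 ± 1.19 and 21.5 ± 1.66 FPKM (SD, n = 3 each; limma adjusted p = 0.102). LIPA, the lysosomal acid lipase, rose from 71.0 ± 1.43 to 85.2 ± 1.93 FPKM (SD, n = 3 each; limma adjusted p = 0.0276) and was the 1 of 9 esterification and lipid droplet genes that passed. ACACB, an acetyl-CoA carboxylase, rose from 1.41 ± 0.114 to 2.26 ± 0.211 FPKM (SD, n = 3 each; limma adjusted p = 0.037) and was the 1 of 21 fatty acid genes that passed. Of 14 isoprenoid genes 0 passed, with PDSS2 at a limma adjusted p of 0.0752, and of 14 catecholamine and glucocorticoid genes 0 passed, with NR3C1 at 0.091. Adjusted over the list alone, 1 esterification gene was higher, 2 fatty acid genes were higher and 1 was lower, and 0 genes of the other lists of this paragraph passed in limma. The camera adjusted p were 0.951 for efflux, 0.749 for esterification, 0.362 for fatty acid synthesis, 0.916 for isoprenoids and 0.362 for catecholamine and glucocorticoid genes. LIPA no longer passed without mock replicate 2 or shHMGB2 replicate 1, 2 or 3 (limma adjusted p from 0.0746 to 0.118), and ACACB without any single library (limma adjusted p from 0.0575 to 0.122).

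Across all genes, 905 of 13409 differed between shHMGB2 and mock in limma, with 442 higher and 463 lower. The largest rises included SAMD9L and RSAD2, both antiviral genes, CFL2, a cofilin, and TNRC6A, a partner of Argonaute proteins. RSAD2 went from 13.7 ± 0.236 to 30.2 ± 0.525 FPKM and TNRC6A from 6.06 ± 0.836 to 13.3 ± 0.979 FPKM (SD, n = 3 each). GBP1, XAF1, HMGA2, FAT2, ANKRD52 and RNF213 completed the 10 largest rises, with log2 fold changes of 1.01, 0.99, 0.97, 0.94, 0.94 and 0.91. Among the largest falls, FOSL1, an AP-1 transcription factor, went from 55.7 ± 2.98 to 17.2 ± 0.654 FPKM, and CCND1, which encodes cyclin D1, from 53.2 ± 3.81 to 20.5 ± 0.600 FPKM (SD, n = 3 each). The EGFR ligands AREG and HBEGF fell by 1.60 and 1.48 on the log2 scale, DUSP6, a phosphatase of ERK, by 1.38, HSPBP1 by 1.41 and PHLDA2 by 1.14. The pseudogene ANAPC1P2 and GAGE12G, 1 of a family of near-identical genes, were also among the largest falls and are uncertain. ANAPC1P2 no longer passed without mock replicate 1 or 2 or shHMGB2 replicate 3 (limma adjusted p = 0.0527, 0.0705 and 0.0569). GAGE12G had 26.6, 1.79 and 13.9 FPKM in the mock libraries and was listed at 0 in each shHMGB2 library; it no longer passed without mock replicate 1 or 3 (limma adjusted p = 0.0664 and 0.0703) or without shHMGB2 replicate 1, 2 or 3 (limma adjusted p = 0.121, 0.112 and 0.108). FAT2 and RNF213 no longer passed without mock replicate 2 or shHMGB2 replicate 1 or 2 (limma adjusted p from 0.0611 to 0.0684).

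Of the 905 genes, 819 were also under an adjusted p of 0.05 in the authors' deposited table with the same direction, and 0 had the opposite direction. The median log2 fold change over all genes was 0.04. The split was 312 higher and 527 lower under upper-quartile scaling, and 349 higher and 571 lower under median-of-ratios scaling. The count was 327 without mock replicate 2 and 320, 290 and 311 without shHMGB2 replicates 1, 2 and 3.

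Genes of the type I interferon response were higher in shHMGB2. Of 30 measured members, 24 rose, 1 fell and 5 did not pass, with a median log2 fold change of 0.54. RSAD2 rose by a log2 fold change of 1.08, XAF1 by 0.99 and IFIT1, an antiviral RNA-binding protein, by 0.84, from 72.3 ± 7.99 to 129.7 ± 8.08 FPKM (SD, n = 3 each; limma adjusted p = 0.0031). The member that fell was IRF7, a transcription factor of interferon genes, from 2.19 ± 0.376 to 1.18 ± 0.236 FPKM (SD, n = 3 each; limma adjusted p = 0.0483). In this list 27 were higher and 1 was lower when adjusted over the list alone. The list passed camera (adjusted p = 1.43e-17) and fry (adjusted p = 0.00118), and did not pass camera with an estimated correlation (adjusted p = 0.185). Of the 10 lists that passed camera, 7 also passed fry, and the stress response, glycolysis and hypoxia, and immediate early lists did not (fry adjusted p = 0.235, 0.121 and 0.126). The count of higher members was 25, 21 and 22 without mock replicates 1, 2 and 3, and 18, 18 and 17 without shHMGB2 replicates 1, 2 and 3. The count of lower members was 0 without mock replicate 1 or 2 or without shHMGB2 replicate 1, 2 or 3.

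Secretory and inflammatory genes were lower. Of 18 measured members, 10 fell, 0 rose and 8 did not pass, with a median log2 fold change of -0.40. AREG fell by 1.60 on the log2 scale, IL1B, an inflammatory cytokine, from 4.48 ± 0.735 to 1.73 ± 0.049 FPKM, and CXCL8, a neutrophil chemokine, from 288 ± 17.5 to 151 ± 20.9 FPKM (SD, n = 3 each). Here 12 were lower and 2 were higher when adjusted over the list alone. The list passed camera (adjusted p = 5.40e-09) and did not pass with an estimated correlation (adjusted p = 0.11). The count of lower members was 5 without shHMGB2 replicate 1 or 2 and 6 without mock replicate 2 or shHMGB2 replicate 3.

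Squamous differentiation genes were lower as well. Of 19 measured members, 8 fell, 1 rose and 10 did not pass. The cornified envelope genes SPRR3, SPRR2E and SPRR1A fell by 0.85, 0.78 and 0.74 on the log2 scale, SPRR3 from 37.0 ± 0.544 to 20.2 ± 1.63 FPKM (SD, n = 3 each). In total 10 were lower and 1 was higher when adjusted over the list alone. The list passed camera (adjusted p = 2.04e-06) and did not pass with an estimated correlation (adjusted p = 0.38). Of 17 basal squamous genes, 5 fell and 1 rose, and adjusted over the list alone 5 fell and 2 rose. The keratins KRT16, KRT14 and KRT6A fell by 0.81, 0.55 and 0.54 on the log2 scale (camera adjusted p = 0.0354; adjusted p = 0.488 with an estimated correlation). The count of lower squamous differentiation genes was 3 without mock replicate 2 and 4 without shHMGB2 replicate 1, 2 or 3, and the basal list did not pass camera under quantile normalization (adjusted p = 0.272) or without mock replicate 2 or 3 or shHMGB2 replicate 3 (adjusted p = 0.0554, 0.122 and 0.0805), and its median was 0.04 without mock replicate 3 against -0.04 with all libraries.

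Cell cycle lists held few called genes, and several p53 targets were lower. Of 32 genes of DNA replication and G1/S, 4 fell and 1 rose, with the same counts adjusted over the list alone. UHRF1, which maintains DNA methylation, fell from 33.3 ± 1.23 to 17.2 ± 0.631 FPKM, and E2F1 from 11.6 ± 0.541 to 7.54 ± 0.361 FPKM (SD, n = 3 each), while MCM10 fell by 0.35 on the log2 scale. The list's median was 0.05 and its mean -0.01, and its camera test, which pointed down, did not pass (adjusted p = 0.922). Of 31 mitosis genes 1 rose, NUSAP1, a spindle protein, with a log2 fold change of 0.25, and adjusted over the list alone 0 passed in limma. The list passed camera (adjusted p = 0.0259; adjusted p = 0.488 with an estimated correlation). Of 20 p53 targets, 5 fell and 1 rose, and adjusted over the list alone 7 fell and 3 rose. PLK3, CDKN1A, the inhibitor p21, and MDM2, which degrades p53, fell by 0.90, 0.88 and 0.57 on the log2 scale (camera adjusted p = 0.0354; adjusted p = 0.448 with an estimated correlation). The count of lower p53 targets was 2 without mock replicate 2 or shHMGB2 replicate 2 and 3 without shHMGB2 replicate 1 or 3, and the list did not pass camera without mock replicate 2 or 3 or shHMGB2 replicate 3 (adjusted p = 0.0543, 0.101 and 0.054). NUSAP1 no longer passed without any single library (limma adjusted p from 0.0555 to 0.155), MCM10 without any except mock replicate 1 (0.0552 to 0.097), and MDM2 without mock replicate 2 or shHMGB2 replicate 1 or 2 (0.0648 to 0.0676), and the mitosis list did not pass camera without mock replicate 2 or shHMGB2 replicate 3 (adjusted p = 0.0554 and 0.054).

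**Figure D2:**
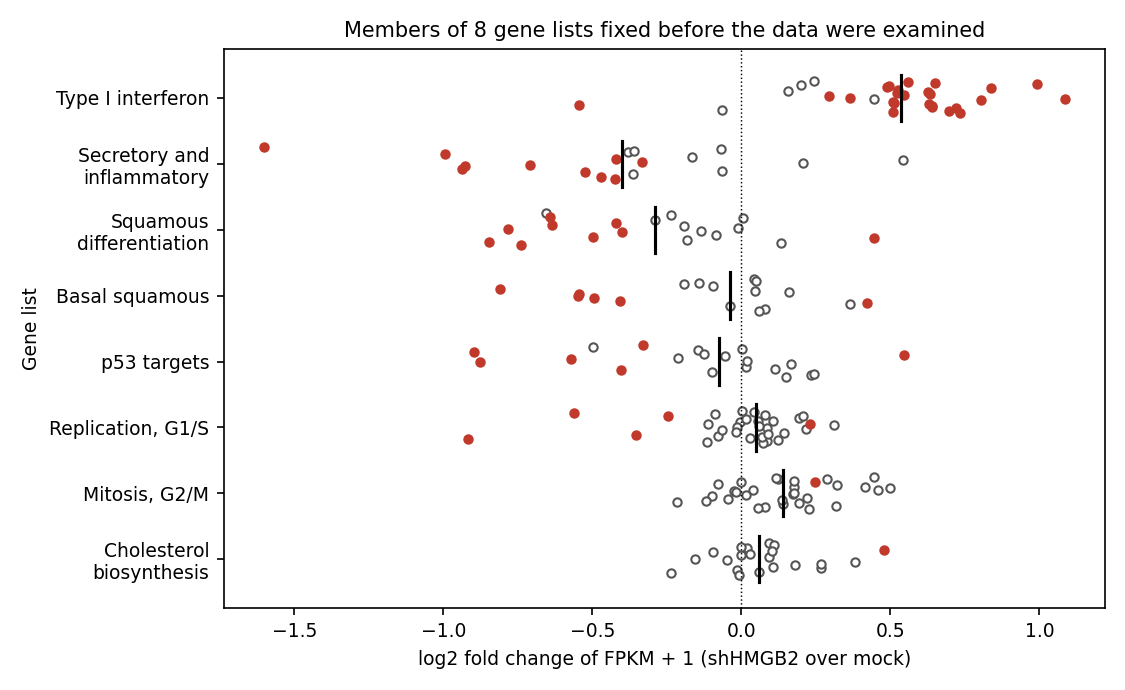
Log2 fold change of FPKM + 1, shHMGB2 over mock (horizontal axis), for each measured member of 8 gene lists. Each point is a gene, filled red where it passed an adjusted p of 0.05 in limma, and vertical bars are list medians. The interferon list has 24 of 30 members higher, and the cholesterol biosynthesis list 1 of 21.

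Other lists changed in few members. THBS1, a matrix protein, was the 1 of 15 mesenchymal transition genes that passed, falling from 23.2 ± 1.93 to 13.9 ± 0.537 FPKM (SD, n = 3 each; camera adjusted p = 0.0297 for the list, adjusted p = 0.38 with an estimated correlation). The epithelial genes OVOL1 and CLDN1, a tight junction protein, were the 2 of 21 junction genes that fell (camera adjusted p = 0.0537; 0.0381 under upper-quartile scaling). Of 25 stress response genes, VLDLR rose, and CEBPB and DDIT4 fell by 0.38 and 0.34 on the log2 scale (camera adjusted p = 0.0216; adjusted p = 0.494 with an estimated correlation). Of 26 glycolysis and hypoxia genes, ANKRD37 and VEGFA, an angiogenic factor, fell by 0.45 and 0.43 (camera adjusted p = 0.00516; adjusted p = 0.488 with an estimated correlation). MYC, a transcription factor, was the 1 of 17 WNT, MYC and YAP targets that fell, by 0.39 (camera adjusted p = 0.138). Of 27 nuclear genes of oxidative phosphorylation, 13 mitochondrially encoded genes and 22 NRF2 targets, 0 passed in limma; the smallest adjusted p were 0.0983 for NDUFS3, 0.161 for ND6 and 0.0503 for ABCC3. Adjusted over the list alone, the mesenchymal list had 1 higher and 4 lower, the junction list 0 and 4, the stress list 1 and 4, the glycolysis and hypoxia list 0 and 3, the WNT, MYC and YAP list 0 and 1, and the last 3 lists 0 and 0. The NRF2 list's median log2 fold change was -0.02 and its mean 0.006, and camera did not pass for it (adjusted p = 0.547), for oxidative phosphorylation (adjusted p = 0.139) or for mitochondrially encoded genes (adjusted p = 0.293). Leaving out a library ended some of these calls: OVOL1 and ANKRD37 no longer passed without any single library, CEBPB without any except mock replicate 3, VEGFA without any except mock replicate 1, CLDN1 and DDIT4 without mock replicate 2 or any shHMGB2 library, and MYC without any shHMGB2 library (limma adjusted p from 0.0503 to 0.157). Camera no longer passed for the stress list without mock replicate 2 (adjusted p = 0.0555), nor for the mesenchymal or the glycolysis and hypoxia list without shHMGB2 replicate 3 (adjusted p = 0.0587 and 0.0501), and it passed for the junction list without mock replicate 1 or shHMGB2 replicate 1 (adjusted p = 0.046 and 0.0217) and for oxidative phosphorylation without mock replicate 3 (adjusted p = 0.0247). Across all genes tested, 3745 had an unadjusted p under 0.05.

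Signs of handling and markers of other cell types were also read. JUNB was the 1 of 13 immediate early genes that fell, by 0.44 on the log2 scale, and the list passed camera (adjusted p = 0.0297; adjusted p = 0.488 with an estimated correlation). Of 16 replication-dependent histone genes 0 passed in limma, with H2AC6 at an adjusted p of 0.111 and a camera adjusted p of 0.157 for the list. Adjusted over the list alone, 2 immediate early genes were lower and 0 histone genes passed in limma. Fibroblast, leukocyte, endothelial and packaging cell markers had 2, 1, 1 and 1 measured members and were not tested as lists. LUM had 2.57 ± 0.418 and 3.49 ± 0.199 FPKM, and ERG 1.75 ± 0.352 and 1.97 ± 0.125 FPKM, without passing (SD, n = 3 each). CD68 fell from 7.28 ± 0.377 to 4.43 ± 0.210 FPKM, and NEFL rose from 11.6 ± 0.772 to 15.3 ± 0.809 FPKM (SD, n = 3 each). Adjusted over the list alone, 1 fibroblast marker was higher, CD68 was lower and NEFL higher, and ERG did not pass. JUNB no longer passed without shHMGB2 replicate 2 or 3 (limma adjusted p = 0.0711 and 0.0708), NEFL without mock replicate 2 or any shHMGB2 library (limma adjusted p from 0.0615 to 0.118), and the immediate early list did not pass camera without mock replicate 3 or shHMGB2 replicate 1 (adjusted p = 0.123 and 0.085). The histone list passed camera, pointing up, without shHMGB2 replicate 2 (adjusted p = 0.00879).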

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

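Tests that used the authors' deposited table, summed copies of a gene, left out features without a symbol, removed the length trend or left out genes with a heptamer were chosen after the results were seen. HMGB2 was lower and past the limma threshold in each alternative, with log2 fold changes from -2.22 to -2.06. The cholesterol biosynthesis list did not pass camera in any alternative, its median ranging from 0.01 to 0.13, but with array weights 9 of its 21 members were higher and 1 lower, against 1 and 0 (camera adjusted p = 0.0668). The count of changed genes (905, with 442 higher and 463 lower) moved most. It was 412 (167 and 245) with no filter on low values, 4194 (2436 and 1758) with array weights, 31 (8 and 23) at an absolute log2 fold change of at least 1, and 242 (78 and 164) at an adjusted p under 0.01. The thresholds are stricter by construction, and the cause was not tested for the filter or the weights. Leaving out each library gave 290 to 873 genes, 97 to 449 higher and 193 to 446 lower, from fewer samples. The authors' deposited table held 2087 genes under 0.05 (833 and 1254).

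Replicate numbers are shared between the groups, but same-numbered libraries did not deviate together (correlations -0.01, -0.04 and -0.10). With the number as a replicate block, 372 genes passed (138 and 234), and 6 other lists passed camera.

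Of the lists other than cholesterol biosynthesis, which did not pass, 10 passed camera. The number was 6 under quantile normalization, 4 at an adjusted p under 0.01, 0 with an estimated correlation, and 5 to 11 with a library left out. It was 6 without genes that carry a 3' UTR heptamer. The cause was not tested. Over all alternatives, 1184 of 1399 values of named genes kept their side of the threshold, 194 no longer passed and 21 newly passed. For the other lists these were 447 of 504, with 47 and 10. The sign differed in 7 of the values of named genes, of HMGB1 and HMGB3, which did not pass in any alternative, and in 26 of the list medians. A test of counts was not run, since whole reads were not recovered. Depth limits genes with low FPKM most, and shHMGB2 replicate 3 was the shallowest library.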

Other observations

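The gene groups of this part, and the tests of seed pairing, chance among heptamers, lengths, scaling, single libraries and mock replicate 1, were chosen after the results were seen. Genes that read out ERK signalling were lower in shHMGB2. Of 15 measured ERK output and feedback genes, 11 fell and 0 rose, among them FOSL1, DUSP6, CCND1, ERRFI1 and ETV4, with log2 fold changes of -1.64, -1.38, -1.33, -0.95 and -0.71. Of 5 measured EGFR ligands, AREG, HBEGF, EREG and TGFA fell, the last pair by 0.70 each on the log2 scale, and BTC rose by 0.39. Of 28 measured interferon-inducible genes outside the fixed list, 19 rose and 0 fell, among them SAMD9L, GBP1, TRIM22 and TNFSF10, with log2 fold changes of 1.11, 1.01, 0.90 and 0.82. In the small-RNA machinery 2 of 13 genes rose, TNRC6A and ANKRD52. The ERK and interferon-inducible groups also passed camera with an estimated correlation (adjusted p = 0.0198 for both). Adjustment here was over these 4 groups alone, against 25 for the fixed lists. The unadjusted camera p were 0.0077 for ERK and 0.0099 for the interferon-inducible group. The fixed secretory and inflammatory list had a smaller one, 0.0044, and did not pass (camera adjusted p = 0.11). These groups are thus not shown to clear the bar set for the fixed lists. The EGFR ligands and the small-RNA machinery passed camera at the preset correlation but not with an estimated one (adjusted p = 0.112 and 0.28). As groups chosen on these data, none of the 4 is independent evidence.

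Genes with AAAGGTG or AAGGTGA in the 3' UTR were lower in shHMGB2. These 2 sequences had the most negative t of 15759 heptamers over 10995 genes (-13.0 and -12.1, with -6.48 next). Of lower genes 33.0% carried one, against 14.7% of higher and 21.2% of other genes. These shares follow from that choice and add no support. Sequences unlike the site, such as TATTTAT (t = -6.30), also lay below the permutations given next. Either heptamer also went with lower values in the coding sequence (-0.0345, SE 0.0050) and the 5' UTR (-0.0356, SE 0.0146). The lowest t in 100 permutations of the fold changes over genes was -5.14. These permutations treat genes as independent, so chance among heptamers is argued against only under that assumption. The search already had 3' UTR length and GC content in its model, so a refit with them is no further test of either. With transcript length added, the effect of a 3' UTR site was -0.08 (-0.0765, SE 0.0054), close to -0.0761 without it. Transcript length beyond that of the 3' UTR thus did not account for the effect of these heptamers, which were picked on these data. Among genes with a site, those with 2 or more differed from those with 1 by -0.05 (-0.0492, SE 0.012), which is consistent with a hypothesis of seed pairing by a small RNA such as the hairpin guide. AAAGGTGA, which holds both, occurs in the HMGB2 coding sequence on chromosome 4 at 173333114 to 173333121 (GRCh38, minus strand), but 10.5% of the heptamers tested occur in that transcript and the hairpin sequence, whose seed would have to be compared with this site, is not given in the sources used here. With 1 hairpin group, a consequence of less HMGB2 protein cannot be told apart from it.

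The type I interferon list was higher in shHMGB2. Scaling, transcript length and any single library are argued against as the whole cause, since the list's median log2 fold change was at least 0.488 under 3 scalings, 0.558 with the length trend removed and at least 0.513 with a library left out. Transcription of an interferon gene may contribute and stays open. Of 8 listed ligands, 6 were analysed here and 1 had at least 1 FPKM in shHMGB2 and lay above each mock library, IFNE, with 1.54 and 2.14 FPKM on average, and its limma adjusted p was 0.13. IFNB1 averaged 0.823 FPKM in mock and 1.02 in shHMGB2, near the filter. It had 1.23, 1.23 and 0.59 FPKM in shHMGB2 replicates 1, 2 and 3, so it did not lie above each mock library. A response to carrying any hairpin was not tested, since the construct of the mock virus is not given in the sources used here.

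ERK output genes were lower also where their own 3' UTR had no site. The 12 members without either heptamer had a median log2 fold change of -0.447, against -0.393 for the 3 with a site. All 15 members were negative, SPRED2 the least at -0.112, and the group was chosen on these data. Any subset would thus have had a negative median, so the test cannot decide how much sites contribute. An indirect effect through another gene with a site may remain. Among the largest falls, the EGFR ligands AREG and HBEGF, and HSPBP1, carry a site in the 3' UTR. FOSL1, DUSP6, CCND1 and PHLDA2 do not. Whether the falls of AREG and HBEGF follow from their sites, or lower the ERK output genes, was not tested.

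Log2 fold change rose with transcript length across genes (Spearman's rho = 0.222, genes not being independent replicates), and rho was 0.113 without mock replicate 1. Genes called higher had a median transcript length of 2186 bases, against 1566 for genes called lower and 1725 for genes tested. With the length trend removed in each library, 1105 genes passed in limma, 560 higher and 545 lower. The real grouping gave 905 genes and the highest of the other 9 splits gave 4; with 10 splits, of which 1 gave as many, the share cannot fall under 0.05.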
